A study of Caenorhabditis elegans with 12 samples.

How the data were processed

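RNA from 12 C. elegans samples in 4 groups of 3 was sequenced, as described per the labels' protocols: synchronized animals grew at 20 °C to the fourth larval stage, were moved to OP50 or PA14 for 24 h at 25 °C, and 1 µg of total RNA per sample entered library preparation. Groups and replicate numbers came from the labels. The authors deposited 1 table of FPKM (fragments scaled to gene length and library size) for 46960 genes with gene names, identifiers, positions and lengths, per the file headers. Per the submitters' processing notes, HISAT2 2.0.4, HTSeq 0.9.1 and DESeq 1.18.0 were used, while their settings, the strand setting of the counting and the genome build are not given in the sources used here. Reads shared between overlapping genes or near-identical members of a family may therefore be assigned unevenly. Of the gene identifiers, 46817 were found in the reference annotation WBcel235, all overlapping the position given there and 32349 identical to it. Gene names follow the authors' file, and 44017 identifiers also had a symbol in the name table used to match lists.

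In every library, FPKM times the gene length was a whole multiple of 1 step for 100% of values above 0, at a tolerance of 0.05 reads, so reads per gene could be recovered. They summed to between 18304747 and 21552816 per library. The library total that the authors divided by differed from this sum, at a ratio of 0.94 to 1.04 (sum over total), and the ratio was lower in all unc-25 libraries than in all wild-type libraries. One read in a gene of 1 kb was worth 0.0438 to 0.0535 FPKM. Replicates of a group differed by more than counting noise, at a chi-square per degree of freedom of 2.54 to 5.43 over genes with enough reads, so none was treated as a repeated library.

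Values were analysed as log2(FPKM + 1). A fold change on this scale understates the change of low genes. Genes with at least 1 FPKM in at least 3 of the 12 libraries were tested, 13092 in all, of which 12179 were protein-coding. A further 22611 genes were at 0 in every library. limma 3.58.1 in R 4.3.3 fitted the 4 groups together, so that they shared an estimate of the spread, with moderated variances and a mean-variance trend, and Benjamini-Hochberg adjusted p-values under 0.05 over all tested genes counted as changed, with no fold minimum. The comparisons were PA14 against OP50 in each strain, unc-25 against wild type on each bacterium, and the interaction. Errors of log2 changes are standard errors from this fit, with a median of 0.0837 for comparisons of 2 groups.

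Before the data were examined, 33 gene lists were fixed from family names and textbook knowledge, covering immune responses, stress responses, detoxification, metabolism, cuticle, translation, protein turnover, neurotransmission and cell types. All had at least 3 tested members, and 2 names matched no gene. Each list was tested in each comparison with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over all 165 pairs, and again with the correlation estimated from the data. With the preset value 71 pairs passed and with the estimate 3 did: PMK-1 targets and ZIP-2 targets for PA14 in wild type, and ZIP-2 targets for PA14 in unc-25. Textbook lists of immune targets may hold genes known because infection raises them, so a rise on PA14 may be built into these lists. The rotation test fry, which asks whether genes of a list move on balance in 1 direction without comparing them with other genes, passed 119 pairs. Some genes belong to more than 1 list, such as 4 of 15 PMK-1 targets.

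Named genes were chosen by a rule fixed before the data were examined. It took unc-25, and for each comparison of 2 groups the 10 largest rises and 10 largest falls with a gene class name, plus 2 each way without one, among genes past the threshold whose 3 values in each group did not overlap. It also took the 5 smallest adjusted p-values in each direction of the interaction and up to 4 members with the largest changes of each list discussed. Names of the 4 piRNA genes that the rule picked are not printed.

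The procedure was tested on simulated reads with 200 genes changed in wild-type PA14 and 12935 genes tested. A further list of genes was raised there by a smaller amount, and its recovery is not given here. The other 12705 genes were unchanged. The changed genes were drawn above a read minimum and all genes had the same dispersion of 0.0011. Recovery of genes with few reads or a larger spread was therefore not measured. For the PA14 comparison in wild type, the procedure recovered 85.1% of genes changed by 0.5 (log2), 98.5% of those changed by 1 and 100% of those changed by 2, with 10 false calls. The simulated share of changed genes was far below the 31.9% called for this comparison in the data, so these rates may differ there. Alternatives fixed before the data were examined covered the pseudocount, the filter, scaling, the variance model, array weights, a fold minimum, the replicate number as a block and leaving out each library. A further 4 were chosen after the data were seen: limma's voom on recovered reads, scaling to summed reads, a read minimum and removal of a gene length trend. For overlaps of comparisons that share libraries, 100 simulated sets without effect were drawn around those libraries. Figures were drawn with matplotlib 3.10.9.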

Results

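RNA sequencing profiled Caenorhabditis elegans fed on 1 of 2 bacteria, a laboratory food strain of Escherichia coli (OP50) or the pathogen Pseudomonas aeruginosa PA14. Animals were the wild-type strain N2 or unc-25(e156) mutants. With 1 mutant strain and no rescue among the groups, other differences between the strains cannot be told apart from the mutation. The gene unc-25 encodes glutamic acid decarboxylase, the enzyme that makes the neurotransmitter GABA. Larvae of the fourth stage spent 24 h at 25 °C on either lawn. Each of the 4 groups (wild-type OP50, wild-type PA14, unc-25 OP50 and unc-25 PA14) held 3 libraries, 12 in all. Reads per gene, recovered from the FPKM values and gene lengths, summed to between 18304747 and 21552816 per library. Because the labels do not say that replicates came from separate cultures, the p-values measure the spread between these samples, which may be technical. Correlations of log2 values ran from 0.988 to 0.991 within groups and from 0.921 to 0.976 between groups, across genes, which are not independent replicates. On the first principal component, which held 53.1% of the variance, libraries lay in the order wild-type OP50, unc-25 OP50, wild-type PA14 and unc-25 PA14.

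**Figure D1:**
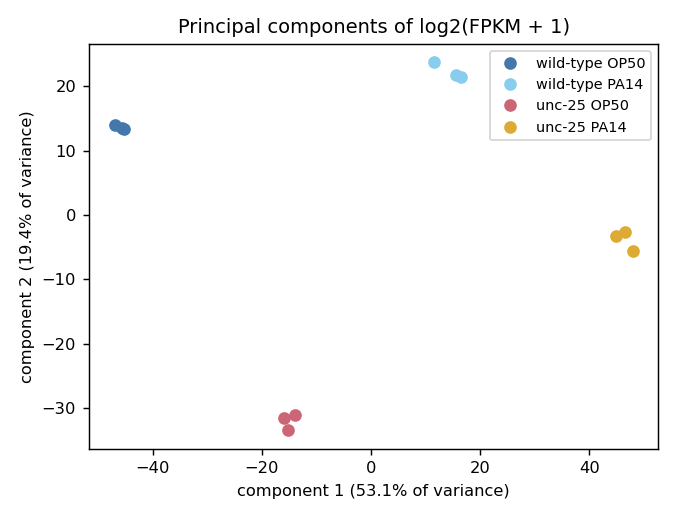
Each point is 1 library on the first (53.1% of variance) and second (19.4% of variance) principal components of log2(FPKM + 1), coloured by group, with 3 libraries per group. The 3 libraries of each group sit together, and the unc-25 OP50 libraries lie between wild-type OP50 and wild-type PA14 on the first component.

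The mutated gene was examined first, as a check of the labels. The unc-25 gene (WBGene00006762) lies at chromosome III, 12942617 to 12949899, plus strand, as the authors' file gives it. Its transcript averaged 4.61 ± 0.479 FPKM (SD, n = 3) in wild-type animals on OP50 and 0.731 ± 0.127 FPKM in mutants on OP50. On PA14 it averaged 4.15 ± 0.433 FPKM in wild type and 1.23 ± 0.23 FPKM in mutants. All 6 mutant libraries lay below all 6 wild-type libraries. The difference between strains was -1.70 ± 0.12 (log2, SE) on OP50 by limma (adjusted p = 3.48e-07) and -1.21 ± 0.12 on PA14 (adjusted p = 8.53e-06). Recovered reads for unc-25 numbered 26 to 49 in mutant libraries and 131 to 186 in wild-type libraries.

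**Figure D2:**
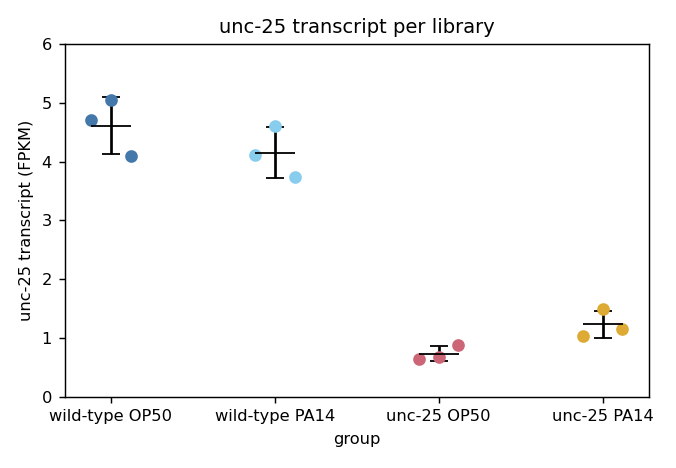
Points give the unc-25 transcript in FPKM (vertical axis) for each of the 3 libraries in the 4 groups (horizontal axis), with a dash at the mean and bars of 1 SD. Wild-type libraries lie between 3.74 and 5.04 FPKM and unc-25 libraries between 0.646 and 1.49 FPKM.

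The first comparison asked which transcripts changed when wild-type animals met PA14. Targets of the immune regulators PMK-1 and ZIP-2 rose. The enzyme genes acdh-1 and acs-2 fell, as did 51 of 88 cuticle collagens (camera adjusted p = 0.138 with an estimated correlation). The largest fall was in acdh-1 (WBGene00016943, chromosome I, 6497436 to 6499560), an acyl-CoA dehydrogenase of propionate breakdown, which went from 632 ± 10.9 to 0.151 ± 0.0529 FPKM (SD, n = 3). The immune response gene irg-5 (WBGene00009429, chromosome V, 13737007 to 13738474) rose from 5.92 ± 0.761 to 296 ± 29.4 FPKM. In all, 4178 of 13092 tested genes changed by limma at an adjusted p under 0.05, 2334 of them higher and 1844 lower on PA14, with 517 rises and 265 falls of at least 2-fold. The direction split depended on scaling, since 55.9% of changed genes were higher with the authors' values, 45.5% after scaling to summed reads and 44.3% after quantile normalization.

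Among named genes in wild type, the largest rises on the log2(FPKM + 1) scale were in B0024.4 (7.51 ± 0.106, SE), C32H11.9 (7.15 ± 0.072) and dod-21 (7.03 ± 0.088). The genes C32H11.9 and dod-21 lie next to each other on chromosome IV. Further rises included irg-5 (5.43), gst-38 (5.03), a glutathione S-transferase, dct-17 (4.71), the C-type lectins clec-4 (4.68) and clec-67 (4.26), the transporter gene pgp-5 (4.51), dod-24 (4.34), irg-1 (4.17) and oac-32 (4.06). Falls were led by acdh-1 (-9.10), followed by acs-2 (-4.76), an acyl-CoA synthetase, acdh-2 (-4.47), F15E6.4 (-4.39), hphd-1 (-4.31), an enzyme of the propionate shunt, and cpr-1 (-4.29), a cathepsin B-like protease. Below these came F18E3.13 (-3.71), folt-2 (-3.59), a folate transporter, pmp-5 (-3.49), clec-47 (-3.41), msra-1 (-3.28), a methionine sulfoxide reductase, and clec-218 (-3.23). Each of these had an adjusted p under 0.05 by limma and FPKM values that did not overlap between the 3 libraries of each group, which chance gives for 10% of genes and which 43.9% of tested genes showed.

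Targets of the p38 MAP kinase PMK-1, a regulator of intestinal immunity, rose together in wild type. Of 15 tested, 12 rose and 1 fell (14 and 1 adjusted over the list alone), with a median of 2.50 and a camera adjusted p of 4.1e-13, or adjusted p = 0.0293 with an estimated correlation. All 6 tested targets of the transcription factor ZIP-2 rose (6 adjusted over the list alone), among them irg-3 (3.93) and irg-2 (3.70), with camera adjusted p = 1.29e-08 and adjusted p = 0.0293 with an estimated correlation. Both target lists came from textbook knowledge and may hold genes known to rise in infection, so their rise here may not be independent of that choice. Of 87 C-type lectins, 37 rose and 17 fell (42 and 18 adjusted over the list alone; camera adjusted p = 0.00164, adjusted p = 0.0963 with an estimated correlation). Lysozymes went both ways, with 5 of 11 higher and 5 lower, both over all genes and adjusted over the list alone, including lys-2 (3.07) and lys-4 (-2.71; camera adjusted p = 0.968). Of 17 genes of the intracellular pathogen response, 6 rose and none fell (6 adjusted over the list alone), led by pals-24 (2.83) and pals-23 (2.66), with camera adjusted p = 0.00118 and adjusted p = 0.128 with an estimated correlation. Glutathione S-transferases rose in 14 of 36 and fell in 4 (14 and 4 adjusted over the list alone; camera adjusted p = 0.0129, adjusted p = 0.272 with an estimated correlation).

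Cuticle collagens fell in 51 of 88 tested genes and rose in 1 (54 and 1 adjusted over the list alone), with a median of -0.54, among them col-93 (-2.35) and col-80 (-2.20). Their camera adjusted p was 8.79e-13, and the adjusted p = 0.138 with an estimated correlation. Epidermal antimicrobial peptides fell in 7 of 13 and rose in none (7 adjusted over the list alone), including cnc-2 (-1.42) and nlp-29 (-0.84), with camera adjusted p = 0.000222 and adjusted p = 0.16 with an estimated correlation. Early embryo markers fell in 18 of 39 and rose in 2 (19 and 2 adjusted over the list alone; camera adjusted p = 2.09e-05, adjusted p = 0.0963 with an estimated correlation). Germ line and oocyte markers rose in 16 of 30 and fell in 1 (17 and 1 adjusted over the list alone), with a median of 0.09, camera adjusted p = 0.00331 and adjusted p = 0.451 with an estimated correlation. Sperm markers varied between libraries of 1 group, with mean deviations from the average of 12 libraries of 0.77, 1.31 and -0.23 (log2) in wild-type OP50 replicates 1, 2 and 3, and only 2 of 29 rose and 3 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.0392, adjusted p = 0.615 with an estimated correlation). The median of the sperm markers was -1.06 with all libraries, and the call was lost without wild-type OP50 replicate 1 (median -0.03) or 2 (-0.02) and without wild-type PA14 replicate 1 (-0.11), 2 (-0.82) or 3 (-0.89). Without wild-type OP50 replicate 3 the median was -1.64.

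**Figure D3:**
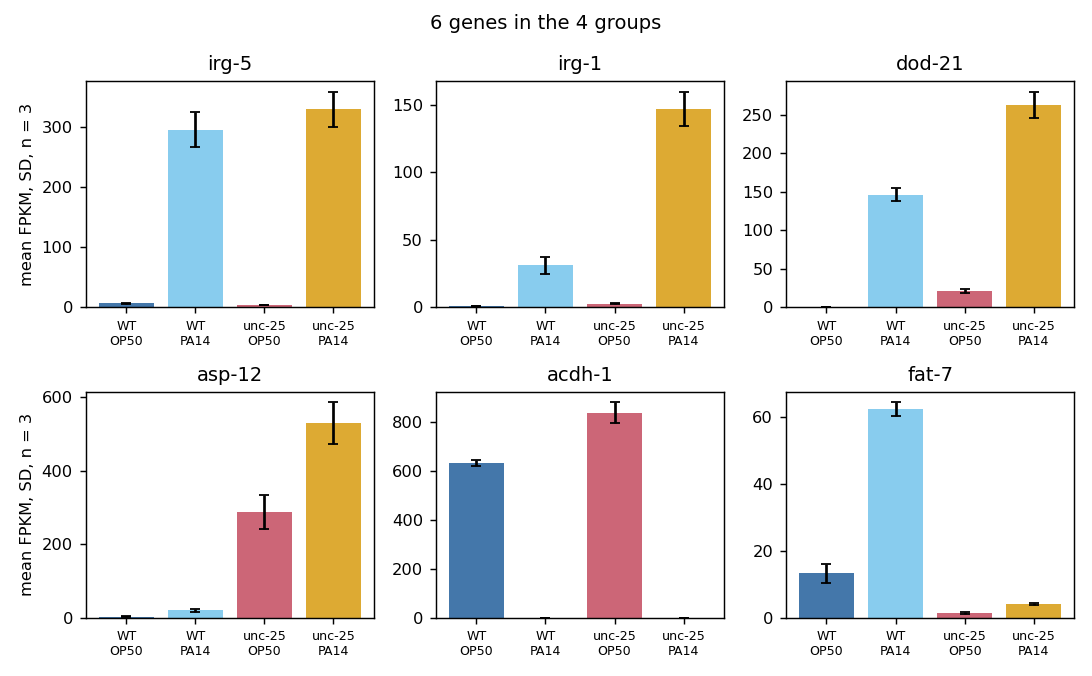
Bars give mean FPKM (vertical axis, from 0) in the 4 groups (horizontal axis, WT for wild type) for 6 genes, with error bars of 1 SD over 3 libraries. The irg-5 mean rose on PA14 in wild type from 5.92 to 296 FPKM, acdh-1 fell from 632 to 0.151 FPKM, and asp-12 stood at 3.16 FPKM in wild-type OP50 and 287 FPKM in unc-25 OP50.

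The second comparison asked the same question in unc-25 mutants. The genes irg-5, clec-4 and irg-1 rose and acdh-1, acs-2 and hphd-1 fell here too, and 77 of 79 ribosomal protein transcripts rose (camera adjusted p = 0.127 with an estimated correlation). The largest rise among genes with a class name was in irg-5, from 3.30 ± 0.136 to 330 ± 29 FPKM (SD, n = 3), and acdh-1 fell from 837 ± 42.1 to 0.337 ± 0.223 FPKM. By limma, 5755 of 13092 genes changed, 3055 higher and 2700 lower, with 576 rises and 375 falls of at least 2-fold. Of the changed genes 53.1% were higher, against 41.3% after scaling to summed reads.

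Rises in unc-25 on the log2 scale included irg-5 (6.26 ± 0.09, SE), clec-4 (5.94), pgp-5 (5.79), irg-1 (5.42), T01D3.6 (5.30), gst-38 (5.25), F11D11.3 (5.18), oac-32 (5.16), the lysozyme lys-2 (4.57), parg-2 (4.21), ugt-31 (4.13), a UDP-glucuronosyltransferase, and irg-3 (4.12). Falls included acdh-1 (-9.30 ± 0.09), the proteases cpr-5 (-5.19), cpr-4 (-4.54) and cpr-1 (-4.42), acs-2 (-4.88), F58G6.9 (-4.73), C23H5.8 (-4.39), ilys-5 (-4.30), hphd-1 (-4.18), sodh-1 (-4.13), an alcohol dehydrogenase, folt-2 (-3.94) and lys-4 (-3.87). All had an adjusted p under 0.05 by limma.

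The 77 rises among 79 ribosomal proteins, with 1 fall (77 and 1 adjusted over the list alone), had a median of 0.42 and a camera adjusted p of 3.63e-30, or adjusted p = 0.127 with an estimated correlation. Mean deviations of this list from the average of 12 libraries were -0.28 to -0.25 (log2) in unc-25 OP50 and 0.14 to 0.17 in unc-25 PA14. The rise therefore shares its unc-25 OP50 libraries with the fall in mutants on OP50 given below and is not independent of it. Proteasome subunits rose in 31 of 33 (31 adjusted over the list alone), with a median of 0.19, camera adjusted p = 3.51e-10 and adjusted p = 0.0963 with an estimated correlation. All 6 ZIP-2 targets rose, also adjusted over the list alone (camera adjusted p = 2.41e-08, adjusted p = 0.0293 with an estimated correlation). Targets of PMK-1 rose in 11 of 15 and fell in 1 (11 and 1 adjusted over the list alone), with a median of 1.20, camera adjusted p = 8.19e-07 and adjusted p = 0.0667 with an estimated correlation. C-type lectins rose in 33 and fell in 35 of 87, also adjusted over the list alone, with camera adjusted p = 0.809. Early embryo markers fell in 24 of 39 and rose in 3 (26 and 3 adjusted over the list alone; camera adjusted p = 2.09e-05, adjusted p = 0.0963 with an estimated correlation). Genes of the mitochondrial unfolded protein response fell in 10 of 14 and rose in 1 (11 and 1 adjusted over the list alone), among them the chaperone hsp-6 (-0.83), with camera adjusted p = 8.09e-05 and adjusted p = 0.0949 with an estimated correlation. FMRFamide-like neuropeptides rose in 15 of 30 and fell in 1 (17 and 1 adjusted over the list alone; camera adjusted p = 0.014, adjusted p = 0.336 with an estimated correlation). Genes changed in the same direction in both strains numbered 1561 higher and 1266 lower, against 544.6 and 380.3 for independent lists of these sizes. The log2 fold changes correlated across genes with Pearson's r of 0.715 and Spearman's rho of 0.569.

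The third comparison asked which transcripts differed between mutants and wild type on the OP50 food. On OP50, transcripts of 39 of 87 C-type lectins, 10 of 11 lysozymes and 14 of 17 intracellular pathogen response genes were higher in mutants than in wild type, with a camera adjusted p of 0.0667 for each list with an estimated correlation. Transcripts of 5 of 6 yolk proteins, 70 of 79 ribosomal proteins and 32 of 33 proteasome subunits were lower, with camera adjusted p = 0.154, 0.138 and 0.0667 with an estimated correlation. The aspartyl protease gene asp-12 (WBGene00017678, chromosome V, 8269254 to 8272058) rose from 3.16 ± 0.298 to 287 ± 46.1 FPKM (SD, n = 3). The yolk protein gene vit-3 fell from 1070 ± 41.6 to 191 ± 10.9 FPKM. By limma, 5230 of 13092 genes changed, 2719 higher and 2511 lower in mutants, with 530 rises and 112 falls of at least 2-fold. Higher genes made up 52% of changed genes with the authors' values, 73.3% after scaling to summed reads and 40.2% after quantile normalization.

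Rises in mutants on OP50 were led by Y37H2A.14 (6.33 ± 0.11, SE) and asp-12 (6.10 ± 0.136), followed by F33H12.7 (5.4), clec-60 (5.38), dct-17 (4.77), ech-9 (4.52), an enoyl-CoA hydratase, ugt-18 (4.34), dod-21 (4.26), clec-172 (3.55), cpr-3 (3.48), asp-17 (3.47) and clec-174 (3.35). Falls were smaller and included pud-3 (-3.41 ± 0.282), the collagen col-43 (-3.09), dod-3 (-2.78), fat-7 (-2.53), a fatty acid desaturase, pud-4 (-2.52), vit-3 (-2.48), clec-218 (-2.39), scl-2 (-2.16), gpdh-1 (-2.09), a glycerol-3-phosphate dehydrogenase, and vit-1 (-2.08). All had an adjusted p under 0.05 by limma.

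Genes of the intracellular pathogen response rose in 14 of 17 and fell in none (14 adjusted over the list alone), with a median of 1.01, including pals-6 (2.32), camera adjusted p = 4.78e-07 and adjusted p = 0.0667 with an estimated correlation. Lysozymes rose in 10 of 11 and fell in 1 (10 and 1 adjusted over the list alone), led by lys-5 (3.04), with lys-7 (-1.92) the exception. Their camera adjusted p was 0.000278, and the adjusted p = 0.0667 with an estimated correlation. C-type lectins rose in 39 of 87 and fell in 9 (41 and 10 adjusted over the list alone; camera adjusted p = 3.92e-05, adjusted p = 0.0667 with an estimated correlation). Saposin-like proteins rose in 15 of 20 and fell in 2 (15 and 3 adjusted over the list alone), among them spp-23 (2.80), with camera adjusted p = 3.37e-06 and adjusted p = 0.0809 with an estimated correlation. Targets of PMK-1 rose in 12 of 15 and fell in 3, also adjusted over the list alone (median 1.08, camera adjusted p = 0.000118, adjusted p = 0.0809 with an estimated correlation). Intestine markers rose in 10 of 16 and fell in 3, also adjusted over the list alone, led by the protease asp-1 (2.55), with camera adjusted p = 0.000586 and adjusted p = 0.0809 with an estimated correlation. FMRFamide-like neuropeptides rose in 18 of 30 and fell in 1 (21 and 1 adjusted over the list alone), with flp-15 (1.29) the largest, camera adjusted p = 3.21e-05 and adjusted p = 0.136 with an estimated correlation.

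Ribosomal proteins fell in 70 of 79 and rose in 2 (71 and 3 adjusted over the list alone), with a median of -0.31, camera adjusted p = 8.71e-28 and adjusted p = 0.138 with an estimated correlation. The fall was smaller under quantile normalization, with a median of -0.08 and 40 genes lower, where the median of all tested genes was -0.05. Proteasome subunits fell in 32 of 33 (32 adjusted over the list alone), with a median of -0.26, camera adjusted p = 2.88e-17 and adjusted p = 0.0667 with an estimated correlation. Vitellogenins, the yolk proteins, fell in 5 of 6 (5 adjusted over the list alone), with a median of -1.37, camera adjusted p = 5.24e-06 and adjusted p = 0.154 with an estimated correlation. Germ line and oocyte markers fell in 22 of 30 and rose in none (24 adjusted over the list alone), with a median of -0.13, camera adjusted p = 4.5e-08 and adjusted p = 0.202 with an estimated correlation. That call was lost after quantile normalization (median -0.06, against -0.05 over all tested genes). Cuticle collagens fell in 24 of 88 and rose in 3, also adjusted over the list alone (camera adjusted p = 0.000424, adjusted p = 0.403 with an estimated correlation). Sperm markers fell in 10 of 29 and rose in 3 (13 and 3 adjusted over the list alone; median -1.08, camera adjusted p = 0.0643). The median was -0.05 without wild-type OP50 replicate 1, -0.07 without replicate 2, and -1.75 and past the threshold without replicate 3, and it was -0.10 without wild-type PA14 replicate 1. Apart from unc-25 itself, no gene of GABA signalling reached a log2 change of 1, and 2 of 7 fell, also adjusted over the list alone (median 0.05, camera direction downward, adjusted p = 0.331), these being unc-25 and the GABA transaminase gta-1 (-0.37). The GABA signalling median turned negative without wild-type OP50 replicate 2 and without unc-25 OP50 replicate 1 or 2.

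Changes in mutants on OP50 overlapped those that PA14 caused in wild type. Of the 2334 genes higher on PA14, 1332 were also higher in mutants, against 484.7 for independent lists of these sizes, and 551 genes were lower in both, against 353.7. These comparisons share the wild-type OP50 libraries, so part of the excess may come from those libraries. The covariance of the log2 fold changes was 0.148, against a mean of 0.014 in 100 simulated sets of groups without any effect around the same libraries, a difference of 0.134. The simulated sets held only the fitted spread between replicates. A shift common to the wild-type OP50 libraries, which would enter both comparisons, was not simulated. Pearson's r across genes was 0.508 (Spearman's rho 0.434), and the mean simulated r was 0.502. Groups without effect that share libraries give such an r whatever the size of the spread. The r therefore cannot say how much of the observed relation comes from the shared libraries.

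**Figure D4:**
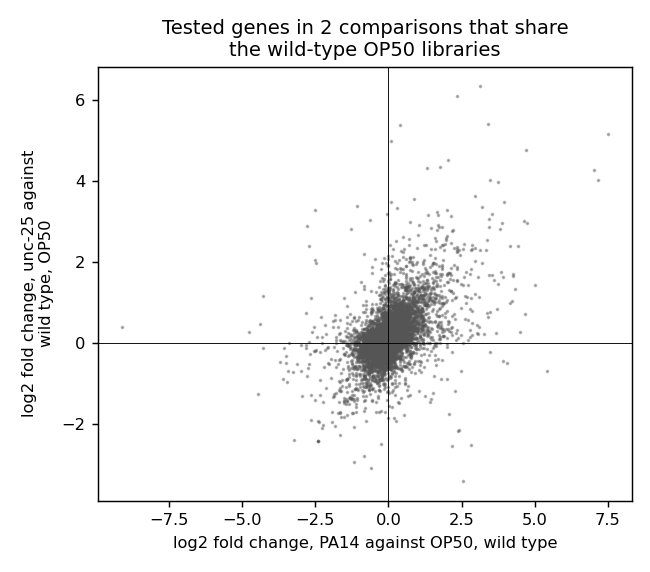
Each point is 1 of 13092 tested genes, with the log2 fold change of PA14 against OP50 in wild type on the horizontal axis and of unc-25 against wild type on OP50 on the vertical axis. The cloud tilts upward with Pearson's r of 0.508 across genes, and simulated groups without effect around the shared wild-type OP50 libraries gave a mean r of 0.502. The covariance was 0.148, against a mean of 0.014 in those simulated groups.

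The fourth comparison asked which transcripts differed between mutants and wild type on PA14. In mutants on PA14, 26 of 30 FMRFamide-like neuropeptides, 15 of 24 pan-neuronal, 11 of 14 pharynx and 12 of 16 intestine markers were higher than in wild type on PA14, with camera adjusted p = 0.0809, 0.0809, 0.172 and 0.0809 with an estimated correlation. Of germ line and oocyte markers 28 of 30, of vitellogenins 6 of 6 and of proteasome subunits 22 of 33 were lower, with camera adjusted p = 0.0968, 0.155 and 0.172 with an estimated correlation, and the proteasome call was also lost after quantile normalization. The protease gene asp-12 rose from 20.1 ± 3.65 to 528 ± 56.5 FPKM (SD, n = 3), and fat-7 (WBGene00001399, chromosome V, 7151353 to 7153146) fell from 62.5 ± 1.97 to 4.22 ± 0.325 FPKM. By limma, 6157 of 13092 genes changed, 3180 higher and 2977 lower, but only 383 rises and 76 falls reached 2-fold. Higher genes made up 51.6% of changed genes, against 68% after scaling to summed reads and 39.9% after quantile normalization.

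Rises on PA14 included asp-12 (4.66 ± 0.136, SE), H02F09.3 (3.22 ± 0.065), pgp-7 (2.60), srw-86 (2.49), fbxa-24 (2.44), parg-2 (2.39), ttr-39 (2.34), ugt-18 (2.31), irg-1 (2.24), clec-60 (2.16) and clec-58 (2.06). Falls included fat-7 (-3.60 ± 0.138), clec-209 (-2.92 ± 0.404), col-43 (-2.73), F56A4.2 (-2.69), ilys-5 (-2.38), scl-2 (-2.38), cpt-5 (-2.31), a carnitine palmitoyltransferase, pud-4 (-1.99), pud-3 (-1.98), ech-1.1 (-1.96) and vit-3 (-1.84). All had an adjusted p under 0.05 by limma.

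FMRFamide-like neuropeptides rose in 26 of 30 and fell in 1 (26 and 1 adjusted over the list alone), with a median of 0.66, led by flp-15 (1.71) and flp-5 (0.96), camera adjusted p = 7.1e-08 and adjusted p = 0.0809 with an estimated correlation. Pan-neuronal markers rose in 15 of 24 and fell in 3 (16 and 3 adjusted over the list alone), among them the neuropeptide processing gene egl-21 (0.77) and the vesicle gene rab-3 (0.64), with camera adjusted p = 0.00157 and adjusted p = 0.0809 with an estimated correlation. Pharynx markers rose in 11 of 14 (11 adjusted over the list alone; camera adjusted p = 0.000141, adjusted p = 0.172 with an estimated correlation). Intestine markers rose in 12 of 16 and fell in 2 (12 and 2 adjusted over the list alone), including elt-2 (0.84), a regulator of intestinal fate, camera adjusted p = 0.000762 and adjusted p = 0.0809 with an estimated correlation. Body wall muscle markers rose in 3 and fell in 5 of 20, also adjusted over the list alone (median 0.01, turning negative without unc-25 PA14 replicate 2, camera direction downward, adjusted p = 0.957), but rose in 6 and fell in 3 after scaling to summed reads. ZIP-2 targets rose in 5 of 6 and fell in 1, also adjusted over the list alone, including F11D11.3 (2.94), with camera adjusted p = 0.00331 and adjusted p = 0.0968 with an estimated correlation. PMK-1 targets rose in 7 and fell in 7 of 15, also adjusted over the list alone (median 0.16, camera direction downward, adjusted p = 0.999). Their median was -0.07, -0.07 and -0.02 without unc-25 PA14 replicate 1, 2 and 3. Immune signalling regulators rose in 23 of 35 and fell in 3 (24 and 3 adjusted over the list alone), among them cebp-1 (1.33), zip-2 (1.01) and tir-1 (0.99), with camera adjusted p = 8.24e-05 and adjusted p = 0.21 with an estimated correlation. Germ line and oocyte markers fell in 28 of 30 (29 adjusted over the list alone), with a median of -0.25, camera adjusted p = 1.37e-14 and adjusted p = 0.0968 with an estimated correlation. All 6 vitellogenins fell, also adjusted over the list alone (median -0.95, camera adjusted p = 7.38e-06, adjusted p = 0.155 with an estimated correlation), and 22 of 33 proteasome subunits fell with none rising (23 lower and 1 higher adjusted over the list alone; camera adjusted p = 2.38e-06, adjusted p = 0.172 with an estimated correlation). The proteasome median was -0.11, and -0.06 after quantile normalization, where the median of all tested genes was -0.05. Genes that differed in the same direction between mutants and wild type on both bacteria numbered 1759 higher and 1591 lower, against 660.4 and 571 for independent lists. Their log2 fold changes correlated across genes with Pearson's r of 0.534 and Spearman's rho of 0.566.

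The fifth comparison tested whether the response to PA14 itself differed between strains, as the interaction of strain and bacterium. It differed for 2329 of 13092 genes by limma, 1092 with a more positive and 1237 with a more negative PA14 effect in mutants, and by at least 2-fold for 157 and 250 of them. The direction split depended on the processing, with 1178 and 1135 after median-ratio scaling, 1039 and 1451 after scaling to summed reads, and 1225 and 1209 with a pseudocount of 5. Ribosomal proteins and ZIP-2 targets lay on the positive side and saposin-like proteins on the negative side, with camera adjusted p = 0.0809, 0.0802 and 0.0667 with an estimated correlation. The 5 smallest adjusted p-values on the negative side belonged to dod-19 (-2.03 ± 0.035, log2, SE; adjusted p = 1.51e-11), dct-17 (-3.89 ± 0.094), clec-50 (-1.66 ± 0.044), clec-63 (-1.58 ± 0.044) and hpo-6 (-2.09 ± 0.059). For dod-19, mean FPKM was 100.4 ± 0.528 and 517 ± 2.52 (SD, n = 3) in wild type on OP50 and PA14, and 508 ± 16 and 638 ± 13 in mutants. The 5 on the positive side were lys-2 (1.5 ± 0.069; adjusted p = 3.03e-08), cyp-14A5 (1.80 ± 0.084), a cytochrome P450, dhs-25 (1.40 ± 0.076), cgp-1 (0.79 ± 0.045) and cat-4 (1.48 ± 0.087), which encodes GTP cyclohydrolase. The lysozyme lys-2 went from 79.5 ± 5.8 to 676 ± 17.4 FPKM in wild type and from 93.02 ± 4.92 to 2230 ± 43.4 FPKM in mutants.

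Ribosomal proteins had a more positive PA14 effect in mutants for 72 of 79 genes and a more negative one for none (77 adjusted over the list alone), with a median difference of 0.35, camera adjusted p = 6.01e-45 and adjusted p = 0.0809 with an estimated correlation. This difference is not independent of the fall in mutants on OP50, whose median was -0.31, or -0.08 after quantile normalization (-0.05 over all tested genes). Proteasome subunits had a more positive effect for 19 of 33 (24 adjusted over the list alone; camera adjusted p = 1.53e-10, adjusted p = 0.0963 with an estimated correlation). Saposin-like proteins had a more negative effect for 13 of 20 and a more positive one for none (14 adjusted over the list alone), with camera adjusted p = 5.51e-09 and adjusted p = 0.0667 with an estimated correlation. Mean deviations of this list from the average of 12 libraries were -0.42 to -0.30 (log2) in wild-type OP50 and 0.37 to 0.45 in unc-25 OP50. On PA14 they were -0.09 to -0.02 in wild type and -0.05 to 0.02 in mutants, so the strains differed mainly on OP50. PMK-1 targets were more negative for 9 of 15 and more positive for 3, also adjusted over the list alone (median -0.97, camera adjusted p = 3.92e-05, adjusted p = 0.0809 with an estimated correlation). Here too the strains differed mainly on OP50, with mean deviations of -1.5 to -1.45 in wild type and -0.54 to -0.44 in mutants. On PA14 the deviations were 0.83 to 0.965 in wild type and 1.03 to 1.09 in mutants. C-type lectins were more negative for 33 of 87 and more positive for 13 (36 and 14 adjusted over the list alone; camera adjusted p = 0.000606, adjusted p = 0.0809 with an estimated correlation). On PA14 the mean deviations of the lectins were -0.02 to 0.03 in wild type and 0.16 to 0.21 in mutants, so they were not lower in mutants there. ZIP-2 targets were more positive for 4 of 6 (4 adjusted over the list alone), among them F11D11.3 (2.81) and irg-1 (1.25, but 0.64 and no longer past the threshold with a pseudocount of 0.1), with camera adjusted p = 0.000162 and adjusted p = 0.0802 with an estimated correlation. Cuticle collagens were more positive for 15 of 88 (21 adjusted over the list alone; camera adjusted p = 0.000703, adjusted p = 0.424 with an estimated correlation), with a median of 0.27 that was 0.14 without unc-25 PA14 replicate 2 and 0.17 without wild-type OP50 replicate 2.

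In wild type on PA14, heat shock proteins rose in 4 and fell in 2 of 15 (camera adjusted p = 0.456), the endoplasmic reticulum unfolded protein response rose in 3 and fell in 6 of 19 (0.0643), HIF-1 targets rose in 2 and fell in 5 of 10 (0.118), and DAF-16 class I targets rose in 7 and fell in 8 of 21 (0.379), with 4 and 2, 3 and 6, 2 and 6, and 7 and 8 adjusted over the list alone. After quantile normalization 3 heat shock proteins rose and 4 fell. Lipid metabolism genes rose in 22 and fell in 21 of 64 (24 and 22 adjusted over the list alone; camera adjusted p = 0.32), but 19 and 24 after quantile normalization, and their median of 0.01 and the camera direction, downward, differ in sign, though the median turned negative without wild-type OP50 replicate 3. Cytochrome P450s rose in 19 and fell in 8 of 46 (21 and 8 adjusted over the list alone; camera adjusted p = 0.0643), and UDP-glucuronosyltransferases rose in 19 and fell in 17 of 50 (22 and 19 adjusted over the list alone; camera adjusted p = 0.809), with a median of -0.04, or 0.09 without wild-type OP50 replicate 1, and an upward camera direction. Molting genes rose in 2 and fell in 7 of 19 (2 and 9 adjusted over the list alone; camera adjusted p = 0.0216, adjusted p = 0.402 with an estimated correlation). In mutants against wild type on PA14, insulin-like peptides rose in 9 and fell in 2 of 25, also adjusted over the list alone (camera adjusted p = 0.0689), and genes of acetylcholine signalling rose in 9 of 21 with none falling (9 adjusted over the list alone; camera adjusted p = 0.0443, adjusted p = 0.329 with an estimated correlation). The acetylcholine call, at a median of 0.33, was lost after quantile normalization (median 0.12) and without wild-type PA14 replicate 2 (0.33), unc-25 PA14 replicate 1 (0.37) or unc-25 PA14 replicate 2 (0.29).

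**Figure D5:**
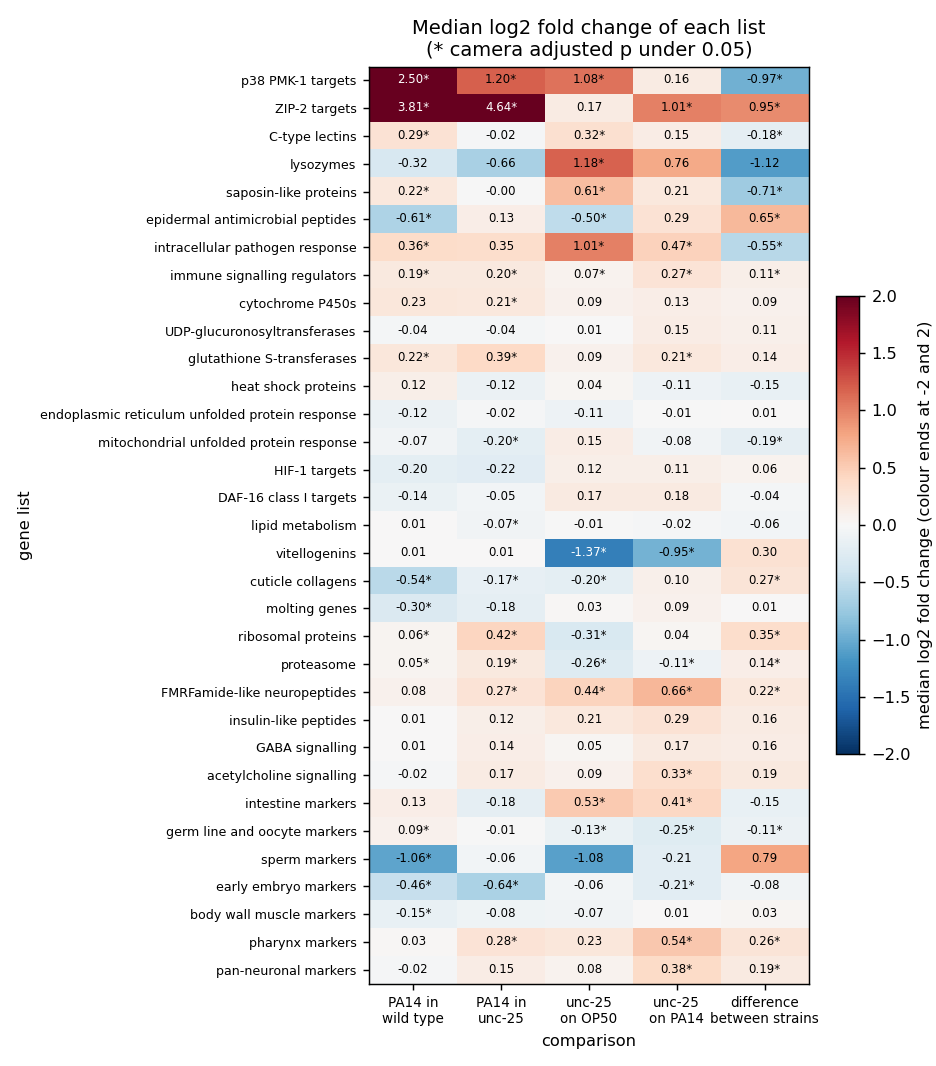
Each cell gives the median log2 fold change of the tested members of 1 of 33 gene lists (vertical axis) in 1 of 5 comparisons (horizontal axis), with colour from blue (lower) to red (higher) ending at -2 and 2. An asterisk marks a camera adjusted p under 0.05, which 71 of 165 list and comparison pairs reached, and 3 of them with an estimated correlation.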

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

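Tests chosen after the result was seen were those of scaling and low read counts for the first pattern and of germ line tissue for the second. Correlation bounds first written for the first pattern were dropped, because groups simulated without effects around the shared libraries already gave a mean r of 0.502 against an observed 0.508. For the second pattern the pair of tissue lists first named, pharynx and body wall muscle, gave a two-sided permutation p of 0.23, and what the ribosomal counts and medians had to show was written anew after they were seen, since the first bound, over 50% of the list, is not the count expected without a change (3065 of all 13092 genes were lower in mutants on OP50 after quantile normalization).

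The PA14 effect differed between strains for 2329 genes by limma's interaction test, which is what brought the lists and genes of this paragraph and the next 2 here. Regrouping strain within each bacterium does not test this count, because the differences between strains enter the regrouped interaction or its spread: of 100 such splits, the real one included, 2 gave as many genes, the other being the exchange of strains on PA14 alone (7207 genes), and the highest count of the rest was 1928. Regrouping thus does not say whether chance can be excluded. For gene lists, each with a camera adjusted p under 0.05 for the interaction at the preset correlation only, the median difference (log2, mutant minus wild type) was -0.97 for PMK-1 targets, 0.95 for ZIP-2 targets, -0.18 for C-type lectins, -0.71 for saposin-like proteins, 0.65 for epidermal antimicrobial peptides and -0.55 for the intracellular pathogen response. It was 0.11 for immune signalling regulators, -0.19 for the mitochondrial unfolded protein response, 0.265 for cuticle collagens, 0.35 for ribosomal proteins and 0.14 for the proteasome. It was 0.22 for FMRFamide-like neuropeptides, -0.11 for germ line and oocyte markers, 0.26 for pharynx markers and 0.19 for pan-neuronal markers. The neuropeptide call was lost without wild-type PA14 replicate 3 (median difference 0.10). The pan-neuronal call, at a camera adjusted p of 0.0498, was lost after quantile normalization (0.15) and in 8 of 12 fits that left out a library: wild-type OP50 replicate 2, wild-type PA14 replicates 1 and 3, each unc-25 OP50 replicate, and unc-25 PA14 replicates 1 and 2 (0.14 to 0.19). The collagen difference was 0.14 without unc-25 PA14 replicate 2 and 0.17 without wild-type OP50 replicate 2.

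Named genes with a more negative PA14 effect in mutants, by log2 difference, were Y37H2A.14 (-5.04), B0024.4 (-4.06), dct-17 (-3.89), ech-9 (-3.88), F33H12.7 (-3.75), dod-21 (-3.42), clec-60 (-3.22), C32H11.9 (-3.12), asp-17 (-2.92), clec-172 (-2.89) and ilys-5 (-2.63). Next came cpr-5 (-2.39), cpr-3 (-2.32), clec-174 (-2.23), F58G6.9 (-2.23), asp-1 (-2.17), spp-23 (-2.17), ech-1.1 (-2.16), hpo-6 (-2.09), dod-19 (-2.03), ugt-18 (-2.03), cpr-4 (-2.02) and clec-209 (-2.02). Smaller differences were those of F56A4.2 (-1.97), pals-6 (-1.95), clec-50 (-1.66), sodh-1 (-1.66), lys-5 (-1.60), clec-63 (-1.58), C23H5.8 (-1.58), asp-12 (-1.45), pals-24 (-1.36) and clec-67 (-1.30). Below these lay lys-4 (-1.16), pals-23 (-1.14), H02F09.3 (-1.11), cpt-5 (-1.08), fat-7 (-1.08), dod-24 (-0.97), hsp-6 (-0.72), ech-6 (-0.26), mthf-1 (-0.24), mmaa-1 (-0.22) and mmcm-1 (-0.10). Many of these genes were named for a large rise in mutants on OP50 or on PA14 in wild type. The interaction subtracts those changes, so a negative value partly follows from the choice. Genes named for a large rise on PA14 in mutants tend to a positive value in the same way.

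Named genes with a more positive effect in mutants were parg-2 (2.99), F11D11.3 (2.81), pgp-7 (2.62), clec-58 (2.06), T01D3.6 (1.82), cyp-14A5 (1.80), clec-218 (1.75), gpdh-1 (1.72), nlp-29 (1.53), lys-2 (1.5), cat-4 (1.48), pud-3 (1.42) and dhs-25 (1.40). Further ones were pgp-5 (1.27), clec-4 (1.26), irg-1 (1.25), acdh-2 (1.24), dod-3 (1.17), oac-32 (1.1), fbxa-24 (1.09), fbxa-128 (1.00), cnc-2 (0.91), irg-5 (0.84), vit-1 (0.84), msra-1 (0.80), zip-2 (0.80) and cgp-1 (0.79). The smallest were F18E3.13 (0.74), vit-3 (0.64), flp-5 (0.59), srw-86 (0.57), gta-1 (0.47), lys-7 (0.43), egl-21 (0.23), mel-32 (0.22) and eif-3.B (0.22).

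The first pattern weighed is that unc-25 mutants on OP50 carried changes that PA14 caused in wild type. The spread between replicates in the shared wild-type OP50 libraries and low read counts do not account for it alone. The covariance of the fold changes was 0.148, and 0.144 among 8957 genes with a mean of at least 100 reads. The highest simulated values, drawn with that spread, were 0.0161 and 0.00521. A shift common to the wild-type OP50 libraries was not simulated. After quantile normalization the covariance was 0.146, against a highest simulated value of 0.0162. This does not decide on library scaling, because a factor per library shifts most genes alike and hardly moves a covariance across genes. Shared genes were not counted under quantile normalization or scaling to summed reads. No biological explanation was tested, and a difference in age or growth between strains was not measured. Part of the overlap may still come from the shared libraries, which with 3 controls could not be divided between the comparisons.

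The second pattern is the lower level of ribosomal protein transcripts in mutants on OP50, called for 70 of 79 genes. The tables argue against a gene length trend as the whole cause, since 72 genes were lower after its removal, with a median of -0.34 against -0.31 before. The authors' scaling cannot be told apart from it. Of the 79 genes, 67 were lower after scaling to summed reads and 70 by median ratios, but 40 lower and 3 higher after quantile normalization, where the median was -0.08 (quartiles -0.13 and -0.03) against -0.31 (-0.35 and -0.28) before. Over all tested genes the median was -0.05 after quantile normalization and 0.01 before. After scaling to summed reads it was 0.09, against -0.22 for the ribosomal proteins. Fewer genes passed after quantile normalization than before because the changes were smaller, while the median SE was 0.03 in both, and no value in the tables decides which scaling holds. A lower share of germ line tissue would raise the markers of all other tissues alike. Intestine markers (mean 0.55) and body wall muscle markers (mean 0.02) differed on OP50 (two-sided permutation test over genes, p = 0.00509, adjusted p = 0.0208 over 12 pairs). Pairs without intestine markers did not differ there by the same test (smallest adjusted p = 0.184). The test takes the genes of a list as independent, and its p-values do not measure the spread between libraries. The share of germ line tissue stays open, because a further change in the intestine would also separate these lists. Ribosomal protein genes were not part of the test. No biological explanation beyond tissue shares was tested.

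For the comparisons of 2 groups, the 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many genes. The real counts were 4178, 5755, 5230 and 6157 (PA14 in wild type, PA14 in unc-25, unc-25 on OP50 and unc-25 on PA14), and the highest counts of the other splits were 5, 4, 2 and 2. Each other split mixes the 2 groups, so differences between them enter its spread and lower its count. These low counts therefore do not show what chance alone would give.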

How the results depend on the processing

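Of the alternatives, 4 were chosen after seeing the data: voom on recovered reads, scaling to summed reads, a mean of at least 10 reads and removal of a gene length trend. The planned count models of edgeR and DESeq2 were not run on the recovered reads, for which only limma's voom was used. Apart from the fold minimum, the counts of changed genes and shared genes stayed within 1.5 times their reported values under each alternative run for them. With a log2 fold change of at least 1, which by its construction keeps fewer genes, the counts were 782 (PA14 in wild type), 951 (PA14 in unc-25), 642 (unc-25 on OP50), 459 (unc-25 on PA14) and 407 (the difference), and the shared genes numbered 191 (unc-25 on both bacteria), 484 (PA14 in both strains) and 295 (PA14 in wild type and unc-25 on OP50). With an estimated correlation 3 list calls remained of 71; the cause was not tested. Leaving out each library in turn gave 3449 to 4130, 4959 to 5826, 4442 to 5284, 5385 to 6091 and 1902 to 2093 changed genes in the order above, 2924 to 3163, 2494 to 2726 and 1562 to 1893 shared genes, 63 to 74 list calls, and an unc-25 difference of -1.76 to -1.64 on OP50 and -1.29 to -1.15 on PA14. That difference depended on the pseudocount, being -2.51 and -1.69 with 0.1 and -0.745 and -0.555 with 5 on OP50 and PA14.

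No named gene or list test changed direction past the threshold under the alternatives run for it. Named genes were not run under quantile normalization or scaling to summed reads, and list tests were not run under the latter. The majority direction of all changed genes did depend on scaling, as given for each comparison. Of 155 named gene values, 9 were over 1.5 times larger and 1 smaller with a pseudocount of 0.1, and 43 were smaller by as much with 5. The gene irg-1 lost its call for the difference with a pseudocount of 0.1 (0.64), and pccb-1 its call on PA14 in wild type in 3 fits that left out a library. Without each unc-25 PA14 library, clec-58 fell under the filter and has no value. For gene lists, leaving out a library ended 31 calls and added 16, quantile normalization ended 8 and added 4 of 165, and a pseudocount of 0.1 ended 2. Replicate numbers as a block gave 4093, 5709, 5257, 6179 and 2225 changed genes and 74 list calls. The labels do not say what the numbers stand for, so samples were not paired. Residual correlations between libraries of the same number ran from -0.04 to 0.07 across genes, none of 18 above 0.1. Their mean was 0.02, against -0.01 between libraries of other numbers. However, 10 of 12 libraries correlated best with a library of their own number, so a weak effect shared by replicate number cannot be excluded. The self-test missed some effects of 0.5 (log2), so smaller changes were not fully detectable at this depth.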

Other observations

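The test of the propionate shunt, the family tests, and the genes listed for the methionine cycle and the vitamin B12-dependent route were chosen after the data were seen. Families were named by the letters before the hyphen of a gene name, and 106 families in 5 comparisons and both directions gave 1060 one-sided Fisher's exact tests, adjusted together. Genes of a family are not independent, so these p-values are descriptive. The F-box genes named fbxb were lower on PA14, 59 of 77 in wild type (median -0.66, adjusted p = 1.99e-30) and 67 of 77 in unc-25 (median -0.75, adjusted p = 1.16e-30), with none higher, and with the same direction under each scaling tried. Examples are fbxb-24 (-1.26) and fbxb-37 (-1.23) in wild type and fbxb-41 (-1.43) in unc-25, all past the limma threshold. In contrast, 56 of 121 fbxa genes were higher and 1 was lower on PA14 in wild type (adjusted p = 1.46e-10), among them fbxa-128 (2.72), and 55 were higher and 7 lower in mutants on OP50 (adjusted p = 5.24e-09).

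Aspartyl proteases of the asp family were higher in mutants on OP50 for 9 of 11 genes and lower for 2 (Fisher's exact test, adjusted p = 0.000443), including asp-17 (3.47) and asp-1 (2.55). On PA14, 7 rose and 1 fell in wild type, while 2 rose and 9 fell in mutants, and the difference between strains was negative for 10 of 11 (median -1.69, adjusted p = 3.22e-08), the same counts under each scaling tried. Translation initiation factors named eif were lower in mutants on OP50 for 23 of 24 genes (median -0.20, adjusted p = 1.09e-11), among them eif-3.B (-0.38), though 14 of them after scaling to summed reads.

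The fall of acdh-1 on PA14 prompted a hypothesis: P. aeruginosa makes vitamin B12, with which worms break down propionate by another route and turn down the propionate shunt to which acdh-1 belongs. The other 4 genes of the shunt fell as well in wild type, hphd-1 (-4.31), ech-6 (-1.80), hach-1 (-1.45) and alh-8 (-0.62), with a median of -1.63 that lay below all 10000 random lists of 4 tested genes (lowest -1.12). In mutants the values were -9.30 for acdh-1 and -2.05 for ech-6. Of 6 genes picked for the methionine cycle, which were not tested as a group, each fell in wild type: sams-1 (-2.18), mthf-1 (-1.15), metr-1 (-0.995), ahcy-1 (-0.87), mel-32 (-0.49) and mtrr-1 (-0.26). The 5 genes picked for the vitamin B12-dependent route, also not tested as a group, did not rise, with falls in mmaa-1 (-0.40), mce-1 (-0.27), pcca-1 (-0.13) and pccb-1 (-0.13) and a value of 0.02 for mmcm-1, which did not pass the threshold. The call for pccb-1 was lost without wild-type OP50 replicate 1 (-0.14) or 3 (-0.11) and without wild-type PA14 replicate 1 (-0.09). The fall of the shunt genes is consistent with a change of bacterial diet, but 0 groups of the design separate infection from food, so these cannot be told apart.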
